A study of Homo sapiens with 13 samples.

How the data were processed

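RNA from 13 flasks was hybridised to 13 Affymetrix HuGene whole-transcript arrays. Samples were grouped by drug exposure and oxygen level per the labels: HepG2 untreated at 20% O2 (n = 3), and HepG2S1 with sorafenib at 20% O2 (n = 4), withdrawn at 20% O2 (n = 3) and with sorafenib at 2% O2 (n = 3). The authors deposited 1 table of log2 values, made with RMA per the submitters' processing notes, which corrects background, normalizes between arrays by quantiles and summarises probes. The log2 scale was read from the range of the deposited values, 2.68 to 14.5. The version of RMA and the annotation release are not given in the sources used here. The quantiles of the arrays were close but not equal. The table holds no detection calls and names no scan date or batch, so that batch and group could not be set apart by it. RMA pulls low signals together, which shrinks folds of genes near the floor.

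The table had 28926 rows. The platform annotation gave 1 gene symbol to 19310 rows, several to 1752 and none to 7864, and symbols were updated through Entrez IDs for 19279 rows with the RefSeq gene table of GRCh38.p14, used for names and chromosomes alone. Rows with 1 symbol entered the tests, and the row with the highest mean stood for each of the 685 genes with more than 1 row, which left 18377 genes. Where a named gene had several rows, they agreed in direction in the comparisons that name it. 1 symbol of the gene lists, an older name of RIGI, was matched through the table's synonyms after a first run had left it out.

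Groups were compared in limma 3.58.1 under R 4.3.3, with lmFit and eBayes in 1 fit over the 4 groups and Benjamini-Hochberg adjustment within each comparison. A gene passed at an adjusted p under 0.05, and counts of 2-fold changes also required a log2 fold change of at least 1. Every log2 fold change is the first group minus the second, and its SE comes from this fit. The flasks were separate, and whether they came from separate cultures is not stated, so that p-values measure the spread between flasks. 30 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01: epithelial junction, mesenchymal, invasion, integrin, hepatocyte, oncofetal, HIF, glycolysis, oxidative phosphorylation, cell cycle, ERK, kinase, growth factor, transporter, NRF2, ATF4, lipid, WNT, NOTCH, TGF-beta, p53, apoptosis, inflammation, interferon, metallothionein and other-cell-type lists. Camera with an estimated correlation and fry were alternatives.

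Genes were named by a rule fixed before the data were examined. It took the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between groups, or 5 and 5 for withdrawn cells against HepG2. It added up to 2 called members with the largest change from each list and a few genes chosen in advance. CA9, 1 of these, had no row with 1 symbol and is not analysed here. The rule named neither unnamed loci nor genes of the Y chromosome.

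The alternatives were trend and robust moderation, the 2 compared groups alone, a filter at the 33rd percentile of mean level, 75th percentile scaling, repeated quantile normalization, array weights, the mean over rows of a gene, all rows, an adjusted p of 0.01 and leaving out each array. A fit of the HepG2S1 arrays alone was chosen after seeing the data. The fit was tested on simulated data for 18377 genes per comparison, with 50 genes changed at each size. For the first comparison it recovered 56% of genes changed by 0.3, 88% of those changed by 0.5 and 100% of those changed by 1 on the log2 scale. False calls numbered 5 of 177 there, 14 of 192 for withdrawal, 6 of 185 for 2% O2 and 11 of 181 for withdrawn cells against HepG2. Far more genes passed in the data, so that these rates do not carry over to them. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.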

Results

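The series measured RNA in HepG2, a human liver cancer line, and in HepG2S1, HepG2 cells kept under long-term sorafenib according to the series title. Sorafenib is a kinase inhibitor used against liver cancer. Each sample was 1 flask on 1 Affymetrix whole-transcript array, and the series design describes the 13 samples as separate flasks. 3 flasks held untreated HepG2 cells and 4 held HepG2S1 cells with 6 µM sorafenib, all at 20% O2. 3 further flasks held HepG2S1 cells withdrawn from the drug at 20% O2, and 3 held HepG2S1 cells with the drug at 2% O2, each for 72 h.

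The arrays had similar ranges, with medians of 7.30 to 7.42 on the log2 scale, and their number limits the precision. Pairs of arrays of the same group correlated at 0.995 to 0.998 across all rows, HepG2S1 arrays of different groups at 0.991 to 0.996, and HepG2 against HepG2S1 arrays at 0.913 to 0.923. The first principal component, with 91.0% of the variance, separated the 3 HepG2 arrays from the 10 HepG2S1 arrays. Among the HepG2S1 arrays the leading component (38.1%) set the 2% O2 arrays apart and the next (30.2%) the withdrawn arrays.

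The first comparison addressed how HepG2S1 cells under the drug (n = 4) differed from untreated HepG2 cells (n = 3). Genes of the hepatocyte secretory program were far lower in HepG2S1. AFP, the fetal serum protein typical of liver cancer cells, had a log2 value of 4.79 ± 0.07 (SD, n = 4) in HepG2S1 and 13.45 ± 0.10 (SD, n = 3) in HepG2. Its log2 fold change was -8.65 ± 0.08 (SE). ALB, the main plasma protein, changed by -7.59 ± 0.06 and APOH, a plasma apolipoprotein, by -8.35 ± 0.09 on the same scale. VIM, an intermediate filament protein of mesenchymal cells, rose by 6.43 ± 0.05, and CDH1, the epithelial cadherin, changed by -4.53 ± 0.08. In limma 10525 of 18377 genes passed an adjusted p of 0.05, 5528 higher and 4997 lower in HepG2S1. Of these, 1553 were higher and 1343 lower by 2-fold or more, and 87 were higher and 159 lower by 16-fold or more. AFP, ALB and APOH lay below 5.76, the median lower quartile of the arrays, in HepG2S1, where array values flatten, so that their folds are limited by that floor.

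Large rises were in EDIL3, an extracellular matrix protein (6.97 ± 0.14), STEAP4, a metalloreductase (6.87 ± 0.11), and SERPINB5, the serpin maspin (6.80 ± 0.06). SRI, MFAP5, ANXA1 and LDHB had log2 fold changes of 6.71, 6.63, 6.59 and 6.43. Large falls, next to AFP and APOH, were in LYZ, lysozyme (-8.36 ± 0.07), ITIH2, an inter-alpha-trypsin inhibitor chain (-7.86 ± 0.06), SPP1, osteopontin (-7.82 ± 0.06), GPC3, a cell-surface proteoglycan (-7.68 ± 0.08), and HP, haptoglobin (-7.52 ± 0.10). On each of these genes all 4 HepG2S1 arrays lay outside the range of the 3 HepG2 arrays. EDIL3, STEAP4, SERPINB5 and SRI had a mean below 5.76 in HepG2, and LYZ, ITIH2, SPP1 and HP in HepG2S1, so that the order of these folds is not settled. The same floor limits the values given below for LGR5, SULT2A1, AKR1B10, PLIN2, SPATA18 and ORM1 in HepG2S1 and for ME1 and DCN in HepG2.

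**Figure D1:**
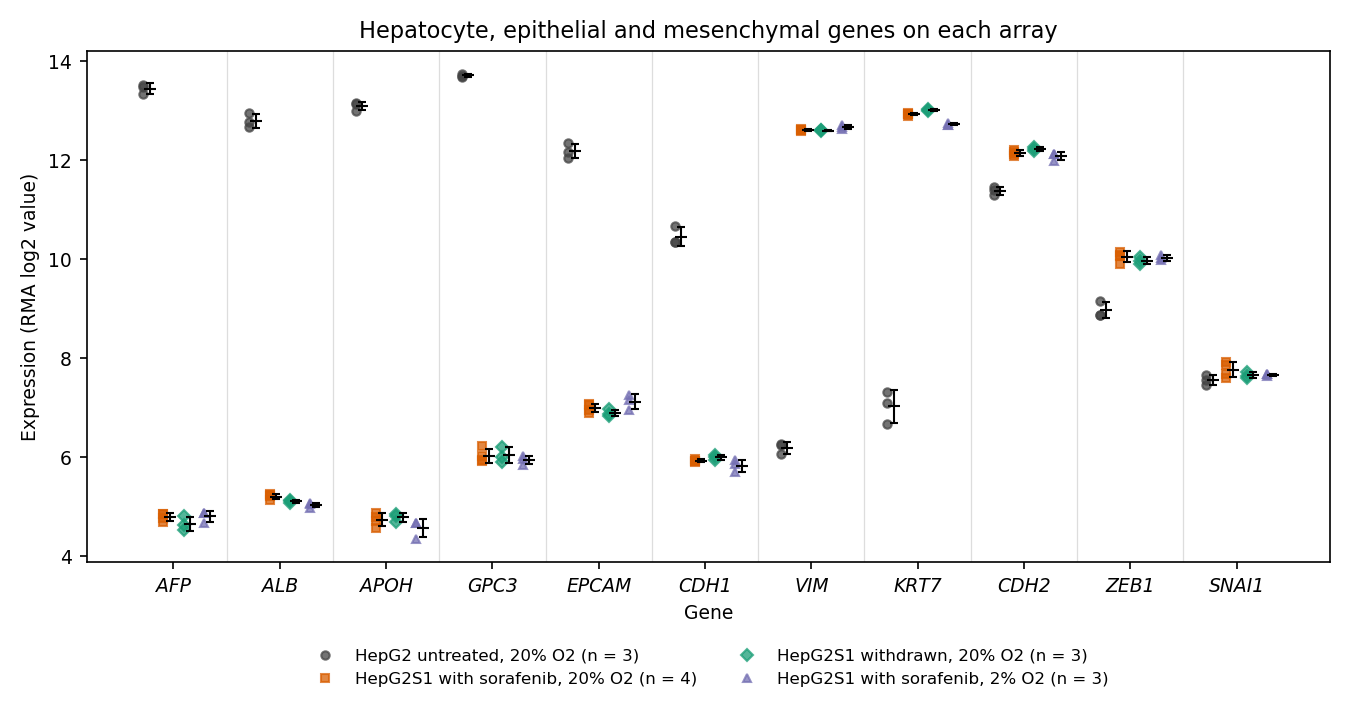
RMA log2 values of 11 genes on each array, with 1 symbol per array and the group mean ± SD in black; the 4 groups are shown by colour. AFP, ALB, APOH, GPC3, EPCAM and CDH1 lay lower and VIM and KRT7 higher on the 10 HepG2S1 arrays than on the 3 HepG2 arrays, whatever the drug or oxygen level.

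All 22 measured hepatocyte secreted proteins fell, with a median log2 fold change of -6.53 (camera, adjusted p = 2.68e-20), and the call held with an estimated correlation (adjusted p = 0.000205 with an estimated correlation). Of 30 cell cycle genes 29 rose and 1 did not pass, with a median of 1.26 (adjusted p = 3.56e-12, and adjusted p = 0.0133 with an estimated correlation). Among them were CCNE2, cyclin E2 (2.97 ± 0.11), and CENPF, a centromere protein (2.56 ± 0.15), and the proliferation marker MKI67 rose by 1.65 ± 0.06. The oncofetal and progenitor list had 13 falls and 2 rises among 18 genes, AFP and GPC3 among the falls. Of 15 WNT targets 12 fell and 2 rose, with LGR5, an R-spondin receptor, at -6.51 and NOTUM, a WNT deacylase, at -4.46. Of 19 hepatocyte transcription factors and enzymes 16 fell and 2 rose; ASGR2, an asialoglycoprotein receptor subunit, was at -4.57, and CPS1, the first enzyme of the urea cycle, rose by 3.46. camera called these 3 lists lower (adjusted p = 8.36e-07, 8.36e-07 and 1.95e-05), and the calls were lost in the same order at adjusted p = 0.0527, 0.0527 and 0.0527 with an estimated correlation.

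Of 20 epithelial junction and keratin genes 14 fell and 4 rose, with EPCAM, an epithelial adhesion molecule, at -5.19 ± 0.08 and KRT7, a keratin, at 5.90 ± 0.10 (camera lower, adjusted p = 0.00808, but adjusted p = 0.0527 with an estimated correlation). The mesenchymal list was not called: 12 of 25 genes rose, 7 fell and 6 did not pass (adjusted p = 0.28). In it VIM rose while SPARC, a matrix protein, changed by -4.97 ± 0.07. CDH2, the neural cadherin, rose by 0.76 ± 0.06 and ZEB1, a repressor of CDH1, by 1.09 ± 0.08. SNAI1, another repressor of CDH1, was at 0.21 ± 0.08 (limma, adjusted p = 0.0281), with overlapping arrays of the 2 groups. This call was lost with the 2 groups alone, 75th percentile scaling or array weights (limma, adjusted p = 0.0715, 0.0714 and 0.125), and without replicate 1 or 3 of HepG2 (0.134 and 0.0588) or replicate 2 or 4 of HepG2S1 (0.0852 and 0.0814). Of 21 invasion proteases and inhibitors 6 rose and 12 fell, with PLAUR, the urokinase receptor, at 1.93 and MMP7, a matrix metalloproteinase, at 1.81 (adjusted p = 0.527). Of 19 integrin and basement membrane genes 9 rose, among them ITGB8 at 3.86, and 10 fell, among them the basement membrane protein NID1 at -5.42 (adjusted p = 0.703).

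Cholesterol synthesis genes were lower, with 13 of 16 down and 2 up (adjusted p = 0.00192, and adjusted p = 0.242 with an estimated correlation); MSMO1, a sterol oxidase, changed by -1.49 and INSIG1, which retains the sterol sensor in the endoplasmic reticulum, rose by 3.03. Of 20 ERK output genes 14 fell and 4 rose, with EGR1 at -3.45 and SPRY4 at -2.83 (adjusted p = 0.00313, and adjusted p = 0.269 with an estimated correlation). Drug transporters and drug metabolism had 13 falls and 6 rises among 22 genes (adjusted p = 0.0119, and adjusted p = 0.26 with an estimated correlation); SULT2A1, a sulfotransferase, was at -5.64 and GSTP1, a glutathione transferase, at 4.71. This direction turned when genes below the 33rd percentile were left out (median 0.24, adjusted p = 0.731). Of 16 p53 targets 9 fell, among them TP53INP1 (-3.49) and SPATA18 (-2.30), and 3 rose (adjusted p = 0.0251, and adjusted p = 0.198 with an estimated correlation). Inflammation and acute phase genes had 12 falls, among them ORM1 (-6.46) and ORM2 (-5.68), both orosomucoids made by the liver, and 8 rises among 23 genes (adjusted p = 0.0275, and adjusted p = 0.269 with an estimated correlation).

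The other lists were not called. Of 16 glycolysis genes 11 rose and 4 fell, with PFKM and PFKP, subunits of phosphofructokinase, at 3.59 and 3.30. Of 29 HIF targets 11 rose and 14 fell, with the glucose transporters SLC2A3 and SLC2A1 at -2.51 and -2.36. Receptor kinases, the class sorafenib inhibits, had 4 rises and 9 falls among 19 genes, with FGFR3 at -3.65 and ERBB3 at -3.01, and KIT, with a mean below 5.76 in both groups, did not pass. Growth factors had 8 rises and 9 falls among 23 genes, with BMP2 at 4.37 and FGF2 at 3.55. NRF2 targets had 6 rises and 13 falls among 20 genes, with ME1, malic enzyme, at 5.45 and AKR1B10, an aldo-keto reductase, at -3.72. Of 15 fatty acid oxidation genes 5 rose and 6 fell, with PLIN2, a lipid droplet protein, at -6.73 and PDK4, which inhibits pyruvate dehydrogenase, at 6.07. Fatty acid synthesis genes had 3 rises and 9 falls among 14 genes, with MLXIPL at -3.12. ATF4 targets and unfolded protein response genes had 8 rises and 11 falls among 24 genes, with DDIT3 at 2.03 and VLDLR at -1.42. Rises and falls numbered 11 and 3 of 21 for oxidative phosphorylation (CYC1 at 0.87), 5 and 2 of 14 for the NOTCH pathway (JAG1 at -1.94), and 7 and 8 of 19 for TGF-beta and YAP targets (CCN2 at -3.75). They numbered 7 and 8 of 17 for apoptosis regulators (PMAIP1 at 2.45), 9 and 7 of 19 for interferon-stimulated genes (HERC5 at 3.04), and 5 and 1 of 9 for metallothioneins (MT1X at 1.01). Some markers of other cell types moved. Of 10 fibroblast and stellate markers 3 rose, DCN, decorin, at 5.43 and LUM among them, and 1 fell, RELN at -5.76. LUM lay at 4.94 to 5.60 on the HepG2 arrays, below 5.76, and at 10.00 to 10.35 in HepG2S1 with sorafenib. Of 11 endothelial and blood markers 1 rose, CD68 at 0.79, and 3 fell. The 19 uncalled lists, the mesenchymal, invasion and integrin lists among them, had adjusted p of 0.0628 to 0.735 in camera. Adjusted over the list alone, the counts were the same in 27 of 30 lists; growth factors and oxidative phosphorylation gained 1 fall each, to 10 and 4, and NRF2 targets 1 rise, to 7. In 5 uncalled lists (invasion, integrins, HIF targets, growth factors, apoptosis) the median, the mean and the test differed in sign.

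Fold changes in this comparison also differed by chromosome. Over the 8904 autosomal genes above the median level, the median log2 fold change was 0.53 on chromosome 18, 0.39 on chromosome 21 and 0.36 on chromosomes 10 and 12, against -0.25 on chromosome 14, -0.24 on chromosome 2 and -0.23 on chromosome 20. The level was the mean over all 13 arrays, most of them HepG2S1, which favours genes high in HepG2S1. Random sets of 1748 of these genes had medians of 0.025 to 0.135, so that the chromosome medians are best read against each other. The SD of the 22 medians was 0.22, against a mean of 0.04 over 10000 random assignments of genes to chromosomes. Cell line and drug history change together in this comparison, so that the effect of the drug cannot be separated from other differences between the lines.

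**Figure D2:**
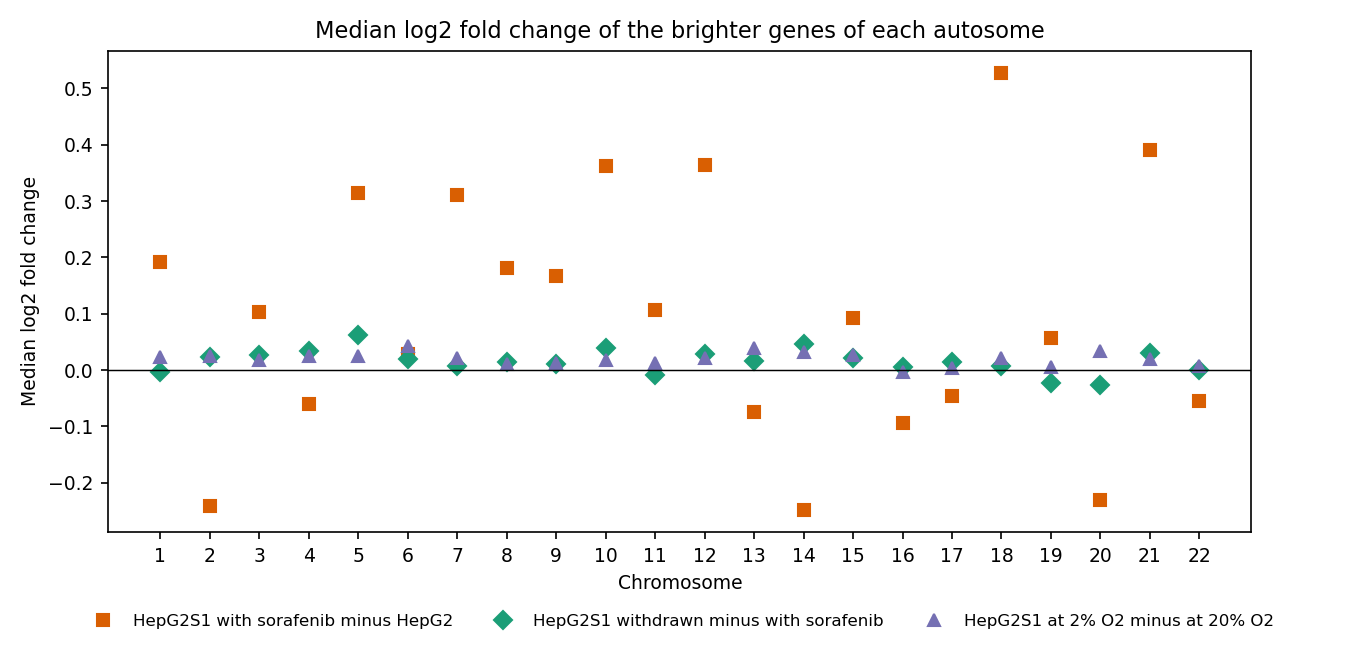
Median log2 fold change of the genes above the median level over all 13 arrays, most of them HepG2S1, on each of the 22 autosomes, 1 symbol per chromosome and comparison. The medians of HepG2S1 with sorafenib against HepG2 ran from -0.25 on chromosome 14 to 0.53 on chromosome 18, while those of the withdrawn and 2% O2 comparisons stayed near 0.

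The next comparison set HepG2S1 cells withdrawn from sorafenib (n = 3) against HepG2S1 cells with the drug (n = 4), which addresses what taking the drug away changes. SERPINB3, a serpin of squamous epithelium, rose by 1.62 ± 0.17 on the log2 scale (SE), EPGN, an EGF receptor ligand, by 1.59 ± 0.10, OLR1, a scavenger receptor, by 1.43 ± 0.11 and IGFBP3, a binding protein of insulin-like growth factors, by 1.33 ± 0.11. THBS1, PTGS2, TIPARP and FAM111B rose by 1.27, 1.24, 1.23 and 1.13. PAPPA2, a protease of IGF binding proteins, changed by -1.42 ± 0.12, DDR2, a collagen receptor kinase, by -1.22 ± 0.09, and ASNS, asparagine synthetase, by -1.07 ± 0.07. WIPI1, ALDH1L2, ARG2, CREB5 and NR1D1 fell with log2 fold changes of -1.10, -1.05, -1.02, -1.02 and -1.01. In limma 3303 of 18377 genes passed, 1852 higher and 1451 lower after withdrawal, and 28 changed by 2-fold or more, 20 higher and 8 lower.

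Of 29 HIF targets 18 rose and none fell, with SLC2A1, a glucose transporter, at 0.99 ± 0.06 and NDRG1 at 0.70 ± 0.05 (median 0.27, camera adjusted p = 8.55e-10); adjusted over the list alone 19 rose and 2 fell. Of 30 cell cycle genes 10 rose and 1 fell, with CCNE2 at 0.97 ± 0.11, RRM2, a ribonucleotide reductase subunit, at 0.96 ± 0.07 and MKI67 at 0.29 ± 0.06 (adjusted p = 1.96e-06; 13 rises and 1 fall adjusted over the list alone). TGF-beta and YAP targets had 9 rises and 1 fall among 19 genes, with F3, tissue factor, at 0.90 and ID2 at 0.78 (adjusted p = 3.07e-05; 12 and 3 adjusted over the list alone). Of 16 glycolysis genes 7 rose, among them ENO2 at 0.54 (adjusted p = 0.000161; 8 adjusted over the list alone). These 4 calls were lost with an estimated correlation, each at adjusted p = 0.137 with an estimated correlation. ERK output genes had 9 rises and 2 falls among 20, with EGR1 at 0.82 and IER3 at 0.68 (adjusted p = 0.0118), also adjusted over the list alone. ATF4 targets and unfolded protein response genes had 10 falls and 5 rises among 24, with ASNS and NUPR1, a stress regulator at -0.97, the largest (adjusted p = 0.0145; 6 rises and 10 falls adjusted over the list alone). Of 16 cholesterol synthesis genes 6 rose, NSDHL at 0.33 and CYP51A1 at 0.31 among them (adjusted p = 0.0186), also adjusted over the list alone. These 3 calls were lost too, each at adjusted p = 0.439 with an estimated correlation.

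Of the epithelial and mesenchymal genes chosen in advance, CDH1 (0.07 ± 0.08), VIM (-0.01 ± 0.05), CDH2 (0.08 ± 0.06), SNAI1 (-0.12 ± 0.08) and ZEB1 (-0.08 ± 0.08) did not pass, nor did AFP, ALB and KIT, whose means lay below 5.76 in both groups. With array weights AFP and KIT passed (limma, adjusted p = 0.0328 and 0.037). Of 25 mesenchymal genes 6 rose, with LOX, lysyl oxidase, at 0.50, and 3 fell, and of 20 epithelial genes 3 rose, with KRT19 at 0.40, and 2 fell, with CLDN7 at -0.33 (4 and 3 adjusted over the list alone). Of 22 hepatocyte secreted proteins 3 rose, RBP4 at 0.63 among them, and 19 did not pass. Of 19 receptor kinases 3 rose, EGFR (0.35) and MET (0.35) among them, and 2 fell. Among fibroblast markers DCN and LUM rose by 0.82 and 0.73. MT1F, a metallothionein, changed by -0.73, CFB, a complement factor, by -0.70 and GDF15, a stress cytokine, by -0.61. camera did not call the mesenchymal, epithelial, hepatocyte, kinase, fibroblast and metallothionein lists, which were among 23 uncalled ones. In 11 uncalled lists the median, the mean and the test differed in sign. With array weights 5231 genes passed.

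The third comparison set HepG2S1 cells with sorafenib at 2% O2 (n = 3) against those at 20% O2 (n = 4), which addresses the response to low oxygen under the drug. Of 29 targets of HIF, the transcription factor stabilised in low oxygen, 28 rose. Among them PFKFB4, a regulator of glycolysis, rose by 2.06 ± 0.11 on the log2 scale (SE), ANGPTL4, an inhibitor of lipoprotein lipase, by 2.03 ± 0.10, ADM, adrenomedullin, by 1.99 ± 0.08, and VEGFA, the angiogenic factor, by 1.02 ± 0.05. Outside that list IGFBP3 rose by 2.85 ± 0.11 and ENO2, an enolase of the glycolysis list, by 2.05 ± 0.07. CD22 changed by -1.17 ± 0.10 and PDK4 by -0.95 ± 0.08. In limma 2786 of 18377 genes passed, 1653 higher and 1133 lower, and of the 80 that changed by 2-fold or more 79 were higher at 2% O2 and 1, CD22, was lower.

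PSORS1C3, SPAG4 and ROPN1L rose by 2.67, 2.15 and 2.10; both rows of PSORS1C3 held the same values. ADGRG1, ARG2, NR1D2, SLC7A2, PLA2G4A and USP2 fell with log2 fold changes of -0.86, -0.84, -0.84, -0.82, -0.77 and -0.74. The HIF targets, of which 1 did not pass, had a median of 1.10 (camera, adjusted p = 1.69e-49, and adjusted p = 0.00327 with an estimated correlation); adjusted over the list alone 28 rose and 1 fell. Of 16 glycolysis genes 13 rose and 1 fell, SLC2A1 at 1.51 ± 0.06 among them (adjusted p = 3.31e-15, and adjusted p = 0.00527 with an estimated correlation; 14 and 1 adjusted over the list alone). TGF-beta and YAP targets had 9 rises and 4 falls among 19 genes, with ID2 at 1.02 and F3 at 0.85 (adjusted p = 0.0081, and adjusted p = 0.334 with an estimated correlation), also adjusted over the list alone. ATF4 targets and unfolded protein response genes had 9 rises and 2 falls among 24, with VLDLR at 0.82 (adjusted p = 0.0495, and adjusted p = 0.651 with an estimated correlation; 10 and 3 adjusted over the list alone). Hepatocyte secreted proteins had 3 falls among 22, VTN at -0.36 among them (adjusted p = 0.0495, and adjusted p = 0.334 with an estimated correlation), also adjusted over the list alone. The median percentile of this list within an array was 18.3 to 19.8 at 2% O2 and 18.6 to 20.1 at 20% O2 with sorafenib. Many members thus lay near the floor in both groups, where small changes are not settled. Of 15 WNT targets 4 fell, ZNRF3 at -0.25 and TBX3 at -0.23 among them (adjusted p = 0.0468, and adjusted p = 0.565 with an estimated correlation; 7 adjusted over the list alone). The ATF4, hepatocyte and WNT calls were lost in 14, 13 and 7 of 22 alternative settings.

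ERK output genes had 4 rises and 8 falls among 20, with SPRY1 and IER3 at 0.99 and 0.87 (camera, adjusted p = 0.48). NRF2 targets had 2 rises, with AKR1C3 at 0.58, and 6 falls, with GSR at -0.42, among 20 (adjusted p = 0.0747; 3 and 6 adjusted over the list alone). LOX and ITGA5, a fibronectin receptor subunit, rose by 1.46 and 0.92 in the mesenchymal list, where 5 of 25 rose and 1 fell. HEY1, a NOTCH target, rose by 1.63, EGFR by 0.72, TGFB2 by 0.79 and MMP7 by 0.80. Rises and falls in their lists numbered 2 and 1 for the NOTCH pathway and 2 and 2 for receptor kinases. They numbered 4 and 3 for growth factors and 3 and 3 for invasion, and camera called none of these 4 lists. Of 30 cell cycle genes 2 rose and 1 fell, which did not pass adjusted over the list alone (camera, adjusted p = 0.368). MKI67 (0.16 ± 0.06) did not pass, but did with trend and robust moderation, the 33rd percentile filter, array weights and without replicate 3 at 2% O2 (limma, adjusted p = 0.0296, 0.0441, 0.0199 and 0.0178). AFP, ALB and KIT, whose means lay below 5.76 in both groups, did not pass. ALB passed under 75th percentile scaling, with array weights, with the HepG2S1 arrays alone and without replicate 2 or 3 of HepG2 (limma, adjusted p = 0.0427, 0.0278, 0.0297, 0.0385 and 0.0497). In 8 uncalled lists the median, the mean and the test differed in sign. Without replicate 2 of the 2% O2 group 1598 genes passed, and 1722 without replicate 1; array weights gave 4568.

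**Figure D3:**
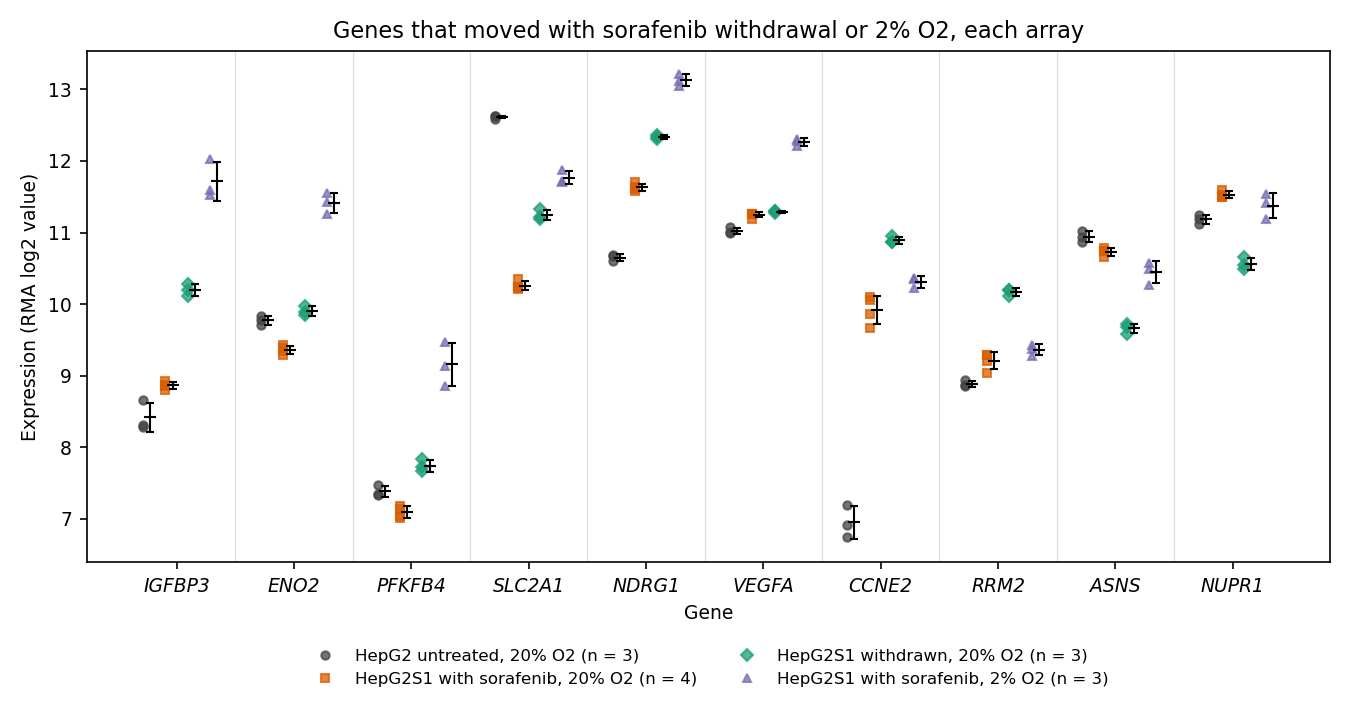
RMA log2 values of 10 genes on each of the 13 arrays, with the group mean ± SD in black; the 4 groups are shown by colour. IGFBP3, ENO2, PFKFB4, SLC2A1 and NDRG1 were higher on the withdrawn and on the 2% O2 arrays than on the arrays with sorafenib at 20% O2. VEGFA was higher at 2% O2, and ASNS and NUPR1 were lower on the withdrawn arrays.

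**Figure D4:**
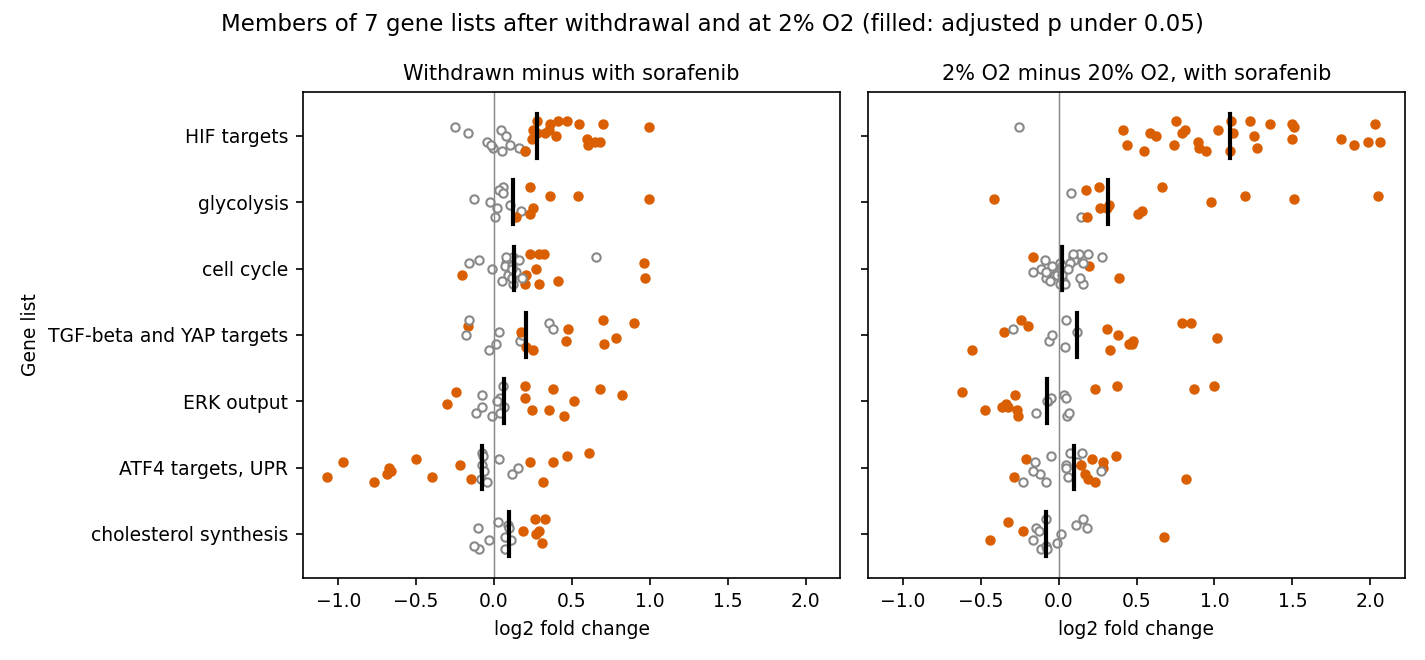
Log2 fold change of each member of 7 gene lists, withdrawn against with sorafenib on the left and 2% against 20% O2 on the right; a filled point passed an adjusted p of 0.05 and the black bar is the list's median. HIF targets had a median of 0.27 on the left and 1.10 on the right.

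The last comparison set withdrawn HepG2S1 cells (n = 3) against untreated HepG2 cells (n = 3), neither with drug in the medium, which addresses what stays different once the drug is removed. AFP changed by -8.79 ± 0.08 on the log2 scale (SE), ALB by -7.68 ± 0.07, LYZ by -8.50 ± 0.08, APOH by -8.31 ± 0.09, ITIH2 by -7.84 ± 0.07 and SPP1 by -7.70 ± 0.07. STEAP4, SERPINB5, MFAP5, EDIL3 and ANXA1 rose by 7.17, 7.09, 6.76, 6.68 and 6.62. VIM rose by 6.41 ± 0.06, KRT7 by 5.98 ± 0.11 and MKI67 by 1.94 ± 0.06. KIT passed at -0.22 ± 0.08 (limma, adjusted p = 0.0216) with a mean below 5.76 in both groups, where the size of a change is not settled, and the call was lost without replicate 1 or 2 of the withdrawn cells or replicate 2 of HepG2 (limma, adjusted p = 0.096, 0.0529 and 0.109). The same floor limits the values of AFP, ALB, LYZ, APOH, ITIH2 and SPP1 in withdrawn cells and of STEAP4, SERPINB5 and EDIL3 in HepG2. In limma 10410 genes passed, 5448 higher and 4962 lower, 2910 of them by 2-fold or more. All 22 hepatocyte secreted proteins fell and all 30 cell cycle genes rose (adjusted p = 3.19e-20 and 5.68e-14), also adjusted over the list alone. Glycolysis genes rose in 12 of 16 and fell in 3, with PFKP at 3.47 (adjusted p = 0.00694, and adjusted p = 0.203 with an estimated correlation), also adjusted over the list alone. camera called 12 lists, 2 higher among them, cell cycle and glycolysis, and 5 held with an estimated correlation. The calls of ERK output, drug transporters, cholesterol synthesis, WNT targets, p53 targets and inflammation, all lower, were lost at adjusted p = 0.443, 0.24, 0.369, 0.0557, 0.127 and 0.203 with an estimated correlation. The direction camera gave for drug transporters turned when genes below the 33rd percentile were left out, with a median of -0.076 against -0.93 (adjusted p = 0.934).

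Of the 10525 genes changed between HepG2S1 with sorafenib and HepG2, 9177 (87.2%) were still changed the same way in withdrawn cells, 67 the opposite way, and 1281 no longer passed. The 4832 genes higher and 4345 lower in both compare with 1639 and 1349 expected if the lists were independent, but part of the excess may come from the HepG2 arrays that both share. The covariance of these fold changes was 1.02, against 0.0035 simulated for unchanged groups. Withdrawal moved 1553 genes (14.8%) back toward the HepG2 level and 1147 further from it, against 940 and 952 expected if the lists were independent. Both comparisons use the same sorafenib arrays; unchanged groups simulated against those arrays gave 0, since almost no gene passed in them, and that value does not measure the shared part. With these arrays divided between the comparisons in 6 ways, 972 to 1205 genes moved back and 627 to 1056 moved further. In each division more genes moved back than further. The divisions called fewer genes, 9796 to 10034 against HepG2 and 1960 to 2982 on withdrawal. The expected counts above hold for the full fit and cannot be set against these. For withdrawal against resistance the covariance was -0.0043, against -0.0026 simulated.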

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

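The gap of the highest or lowest of the 4 arrays of HepG2S1 with sorafenib at 20% O2 was set against the range of the group for 170 named genes and 30 list means. It exceeded Dixon's critical value for 4 arrays in 10 genes and 1 list mean, and chance gives about 1 in 20. Replicate 2 stood apart for ABCC3, a drug transporter (10.4 on the log2 scale, against 10.3 on average in the others), BMF, a pro-apoptotic protein (7.32 against 7.22), and EDIL3 (11.8 against 11.9). Replicate 3 stood apart for PLIN2 (5.80 against 5.74), SAA2, an acute phase protein (7.16 against 7.29), SRI (12.3 against 12.4) and SULT2A1 (5.31 against 5.47). Replicate 4 stood apart for CCN2 (8.24 against 8.34), TIMP3, a metalloproteinase inhibitor (10.7 against 10.8), and VEGFA (11.2 against 11.3). The metallothionein mean was 10.0 in replicate 1 and 10.05 in the others.

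The 9616 rows with no gene symbol or several entered no gene test. Among them 530 changed by 2-fold or more between HepG2S1 with sorafenib and HepG2, 13 on withdrawal, 17 at 2% O2 and 563 between withdrawn cells and HepG2.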

How the results depend on the processing

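Of 2576 list values under alternative settings 2398 kept their direction and side of the threshold, 64 lost a call, 56 gained one and 58 turned direction; of 5949 named gene values 5837 kept both, 96 lost and 11 gained a call and 5 turned. No paired analysis was possible because the numbers in the titles are unique to each flask and the replicate numbers follow accession order alone. With no detection calls, signal over background limits genes near the floor. The causes of the changes below were not tested.

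Array weights gave 4568 changed genes at 2% O2 and 5231 on withdrawal, and an adjusted p of 0.01, a stricter limit by construction, 1298 and 1970. At 2% O2 71.3% of the genes were higher at that limit and 51.2% with array weights, against 59.3%. Leaving out 1 array gave 1598 to 3168 at 2% O2, the lowest without replicate 2 of the 2% O2 group and 1722 without replicate 1. Genes moved back by withdrawal numbered 985, 972, 1009 and 1013 in 4 of the 6 divisions of the sorafenib arrays. Called lists at 2% O2 numbered 3 under 75th percentile scaling and 3 to 7 with 1 array left out, 3 of them without replicate 1 at 2% O2, replicate 3 or 4 with sorafenib at 20% O2, or replicate 2 of HepG2. With an estimated correlation 2, 2, 0 and 5 lists were called for resistance, 2% O2, withdrawal and withdrawn cells against HepG2, and by fry, which does not compare a list with other genes, 24, 15, 14 and 26.

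The directions that turned were of lists uncalled in camera, except drug transporters, and the values are list medians; the test's direction can turn while the median keeps its sign. With genes above the 33rd percentile, drug transporters stood at 0.24 in the first comparison, -0.041 at 2% O2 and -0.076 for withdrawn cells against HepG2, where TGF-beta targets stood at 0.040. In the same setting growth factors (0.021) and the oncofetal list (0.011) turned on withdrawal, and interferon genes (-0.083), p53 targets (-0.018) and kinases (0.019) at 2% O2. Quantile normalization turned drug transporters (-0.037), endothelial markers (-0.041), epithelial genes (-0.011), invasion (-0.037), oncofetal genes (-0.011), p53 targets (-0.069) and kinases (-0.040) at 2% O2. It also turned interferon genes (-0.0022), oncofetal genes (-0.010) and oxidative phosphorylation (-0.022) on withdrawal, and TGF-beta targets (-0.0088) for withdrawn cells against HepG2. Array weights turned interferon genes (-0.043) and kinases (-0.0082) on withdrawal and p53 targets (-0.023) at 2% O2; 75th percentile scaling turned the oncofetal list (-0.057) on withdrawal. Fry turned growth factors (0.012) on withdrawal, invasion (-0.24 in the first comparison and -0.22 for withdrawn cells against HepG2), and p53 targets (-0.030) and kinases (-0.045) at 2% O2. Trend and robust moderation turned p53 targets at 2% O2 (-0.030). The 2 compared groups alone turned oncofetal genes (-0.035) and kinases (-0.012) on withdrawal, and the HepG2S1 arrays alone, a fit chosen after seeing the data, interferon genes (-0.019) and kinases (-0.012).

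With 1 array left out, ranges on withdrawal were -0.016 to 0.027 for growth factors, -0.050 to 0.0025 for interferon genes, -0.072 to 0.012 for oncofetal genes, -0.037 to 0.019 for kinases, -0.048 to -0.035 for epithelial genes and -0.054 to -0.021 for integrins. At 2% O2 they were -0.089 to -0.038 for drug transporters, -0.083 to -0.027 for epithelial genes, -0.030 to -0.0074 for p53 targets and -0.071 to -0.037 for kinases. For withdrawn cells against HepG2 growth factors ranged from -0.015 to 0.039 and TGF-beta targets from 0.0037 to 0.070. AFP at 2% O2 was -0.041 under 75th percentile scaling and -0.041 with array weights, and -0.024 to 0.074 with 1 array left out.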

Other observations

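The tests of chromosomes and of the rank of hepatocyte genes were chosen after the result was seen; the others were not.

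Low oxygen and drug withdrawal moved overlapping sets of genes in HepG2S1. Of the genes higher on withdrawal 606 were also higher at 2% O2, and of those lower 288 were also lower, against 167 and 89.5 expected if the lists were independent, while 79 and 90 moved in opposite ways, against 114 and 130.5. Both comparisons use the same sorafenib arrays; the covariance of their fold changes was 0.015, against 0.0026 simulated for unchanged groups, and their correlation 0.40, against 0.43 simulated. With the sorafenib arrays divided between the comparisons in 6 ways, so that they shared none, the covariance was 0.011 to 0.014 and the correlation 0.26 to 0.37.

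The rise of HIF targets on withdrawal was weighed first. The HIF list was fixed before the data were examined, and its rise comes from the withdrawal comparison alone. Sharing sorafenib arrays with the 2% O2 comparison could therefore not produce it. In the 6 splits the withdrawal median of the list was 0.22 to 0.32. Sharing bears on the genes raised 2-fold at 2% O2, a set chosen in these data. With separate arrays for the 2 comparisons these genes still rose on withdrawal. Their median was 0.33 in the lowest of 6 splits, with 87.5% to 91.0% of them above 0. Shared arrays do not account for all of their rise. The median over the splits was 0.35 for these genes. Lower oxygen at the cells in the withdrawn flasks and a direct effect of the drug on HIF targets both predict a rise. Neither gives its size, so that these 2 accounts cannot be told apart. VEGFA, which rose at 2% O2, did not pass on withdrawal, and oxygen at the cells and cell number are not among the values used here.

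The loss of hepatocyte genes in HepG2S1 was weighed next. A scale difference between arrays, which keeps the order of genes within an array, is argued against by the rank of the hepatocyte secreted list: its median percentile was at most 20.1 on the arrays of HepG2S1 with sorafenib and at least 98.6 on those of HepG2. A different chromosome complement, as cells of another origin or a rearranged clone would have, was set against the chromosome medians. Their SD was 0.22, above the 0.083 that was the highest of 10000 random assignments (1e-04 is the smallest p they can give). The medians ran from -0.25 to 0.53, against -6.53 for the hepatocyte secreted list, all 22 members of which fell. These sizes argue against chromosome-wide shifts alone as the account of the loss of that list. They do not decide whether the cells had another origin. For withdrawn cells against HepG2 the SD was 0.23, against a highest random value of 0.077. On withdrawal the SD was 0.021, above the random mean of 0.012 but below the highest random value of 0.023 (permutation p = 0.001). At 2% O2 the SD was 0.011 (permutation p = 0.3). A small p thus arose within the line too, on withdrawal. Random assignment leaves out neighbouring genes regulated together, so that its p does not measure a chromosome change. Genes on chromosomes 2, 14, 17 and 20, which general knowledge gives as extra in HepG2, had a median of -0.18, but this set was chosen after the medians were seen and holds the 3 lowest, so that its value decides nothing; chromosome 17 alone stood at -0.05. These values do not tell a clone selected under the drug from cells of another origin, and reprogramming by long exposure stays open.

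Other divisions of the same arrays into groups of the same sizes were tested. For HepG2S1 with sorafenib against HepG2, 1 of 35 divisions, the real one, gave as many as 10525 genes, and the highest other gave 7440. For withdrawal 1 of 35 gave as many as 3303, with 953 the highest other, and for 2% O2 1 of 35 gave as many as 2786, with 958 the highest other. In these 3 the share of 1 in 35 lies under 0.05 and is the smallest that 35 divisions can give. Other divisions mix the 2 groups, so that any large difference between the groups puts the real division first, whatever its cause. For withdrawn cells against HepG2 the 10 divisions are too few for a share under 0.05. There 1 gave as many as 10410, the real one, and the highest other gave 0.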
